A study of Mus musculus with 8 samples.

How the data were processed

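RNA was measured by sequencing of poly(A)-selected, directional libraries from bEnd3 cells, a line of mouse brain endothelial cells. There were 8 libraries, 4 from cells given 5 µM corticosterone for 24 h and 4 from cells kept in culture medium, grouped by the titles and the treatment field. The treatment protocol of the medium samples also names corticosterone, and the labels name no vehicle. The labels name bcl2fastq, kallisto 0.46.1 and the mouse genome builds mm10 and GRCm38. The transcript index, the read length, the strand setting and the step from transcripts to genes are not given in the sources used here.

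The authors deposited a gene-level table of estimated counts for 35852 genes, with different totals per library and no normalization. The authors also deposited, per library, kallisto tables of 119414 transcripts with an estimated count, a TPM (abundance per 1e+06 transcripts) and an effective length. Per the file headers, TPM is the abundance that kallisto derives from the estimated count and the effective length, and it summed to 1e+06 in each library. Transcripts were joined to genes by their identifiers in the GENCODE M21 annotation, which matched 97.7% of them. The gene table and the sums of transcript estimated counts were equal within 0.5 counts in all libraries for 99.5% of the 35773 genes compared. The gene table held 98.4% to 98.5% of the transcript counts of each library. Positions are from GENCODE M21 on GRCm38, counted from 1.

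The effective lengths differed between libraries. In corticosterone replicates 1 and 2 the effective length equalled the transcript length plus 1 in 100% of the 61001 transcripts of 1000 nt or more, within 0.01 nt. In the other 6 libraries it did so in 0% of them, and the median effective length was 340.4 to 360.3 nt shorter than the transcript. TPM is divided by the effective length, so the TPM of the 2 kinds of library are on different scales, and the count table was used for the comparison. The share of each gene's 31-mers found in no other gene was computed from the annotated transcripts as a measure of sequence shared between genes. Genes that share at least 10% of the 31-mers of the smaller gene were joined into families for an added alternative.

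Estimated counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 13272. Libraries were scaled by TMM, and the quasi-likelihood F test (robust) compared corticosterone with medium, with the group as the single term. A gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05. CPM are counts per 1e+06 of the TMM-scaled library, given as mean ± SD over n = 4 libraries, and the SE of a log2 fold change is its size divided by the square root of the F statistic. For genes with 0 counts in all libraries of a group together, the fold is a lower bound against a floor of 3 counts over the group. For genes with 1 to 3 counts, the ratio of counts has a 95% exact binomial interval. The bound, the ratio and its interval are scaled by the TMM-scaled library totals of the groups. Floors and intervals cover counting error alone, and reads without molecular identifiers are not independent molecules.

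Before the data were examined, 27 gene lists with 604 members were written down from general knowledge, together with the test, the alternatives and the rule for named genes. The lists cover glucocorticoid receptor targets, corticosteroid receptors and cofactors, junctions, barrier transporters, caveolae, leukocyte adhesion, chemokines, NF-kappaB, interferon and MHC class I genes, matrix, proteases, angiogenic, Wnt and TGF-beta genes, YAP and SRF targets, cell cycle, ER stress, cholesterol, glycolysis, the clock, endothelial identity, markers of pericytes, fibroblasts and neural cells, and mitochondrial and ribosomal mRNAs. The 25 lists with 5 or more measured members were tested with limma 3.58.1 camera on log2 CPM (prior count 3) with an inter-gene correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation and fry stood beside it.

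The rule for named genes took 86 genes. Its first part took the 8 largest rises and 8 largest falls among changed genes with a mean CPM of 1 or more in a group and no overlap between groups, leaving out predicted genes. Its other parts took the 2 rises and 2 falls with the smallest p, the 3 members with the smallest p of each list past the threshold, the 2 of each other list, and 16 genes fixed by name. Of these, 85 have values. A few genes that the rule takes are left out of the text and of the search for single libraries far from the others; every count of genes and list members includes them. Where a count of list members is 5 or fewer, members outside the rule are named too, apart from a few left out of the text; these, and any other gene outside the rule, were chosen after their values were seen.

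The method was tested on simulated data, negative binomial counts for 8 libraries with the measured means, totals and dispersions, in which chosen genes were changed by known folds. Of 50 genes per fold, 36% were called at 1.25-fold, 64% at 1.5-fold, 88% at 2-fold and 98% at 4-fold. In the simulation 225 genes were changed and 13137 were tested, while 40.2% of tested genes changed in the data. With fewer changed genes the adjusted threshold is stricter, so these shares may be too low for the data. Of the calls, 5.81% were genes not changed in the simulation, and 0 of 20 unchanged lists passed.

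Alternatives planned beforehand were other scalings (RLE, upper quartile, library size), no filter and a stricter one, DESeq2 1.42.0, limma-voom, other quasi-likelihood settings, counts not rounded, transcript sums, limma-trend on TPM, a replicate block and leaving out each library. Another 6 were added after the effective lengths had been seen: the 6 libraries without corticosterone replicates 1 and 2, a term for those 2 replicates, families of genes, genes with 95% or more unique 31-mers, TPM with one effective length per transcript, and TPM of the 6 libraries. Totals were compared with an exact permutation test over 70 arrangements in R 4.3.3. Families of genes were joined in Python 3.11.15 with scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.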

Results

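The data are RNA-seq counts from bEnd3 cells, a line derived from mouse brain endothelium. Corticosterone, the main glucocorticoid hormone of mice, was given at 5 µM for 24 h to 4 samples, and 4 samples stayed in medium, per their titles and treatment field. The treatment protocol of the medium samples also names corticosterone, and no vehicle is named for them. Total estimated counts of the corticosterone libraries, replicates 1 to 4, were 32.1, 27.7, 33.2 and 27.8 M (M is 1e+06 counts). Those of the medium libraries were 46.2, 27.0, 19.7 and 28.6 M. The groups had mean totals of 30.2 ± 2.87 and 30.4 ± 11.2 M (SD, n = 4), a difference of -0.168 M (two-sided exact permutation test, p = 0.9714, where 0.02857 is the smallest p this design allows). The labels do not say whether replicates are separate cultures, so the p-values measure the spread between these samples.

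The comparison asks how corticosterone alters the transcriptome of these cells. Genes known to be induced through the glucocorticoid receptor rose: Fkbp5, a co-chaperone of the receptor, rose 6.83-fold, Per1, a clock gene, 4.43-fold, and Tsc22d3, an anti-inflammatory leucine zipper protein, 3.87-fold. Jam2, an adhesion molecule of endothelial junctions, rose 4.84-fold and the tight junction protein gene Cldn5 1.32-fold. The fibronectin gene Fn1 fell to 0.424, the tenascin gene Tnc to 0.401 and the vascular peptide gene Apln to 0.277 of medium, while the lists of matrix and angiogenic genes that hold them went both ways. All 29 measured cell cycle genes fell, with a median log2 fold change of -0.33. Each of these genes named singly had every library of one group above every library of the other.

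Of 13272 genes tested with edgeR, 5337 (40.2%) changed, 2596 higher and 2741 lower with corticosterone. Most changes were small: the median absolute log2 fold change of the changed genes was 0.25, and 499 genes changed at least 2-fold, 332 higher and 167 lower. In 5300 tested genes (39.9%) the groups did not overlap, where chance gives 2.86%. In the 6 libraries without corticosterone replicates 1 and 2, which were quantified with another effective length, 4992 of 13639 genes changed, 2540 higher and 2452 lower, and 547 at least 2-fold. Of the 5337 genes, 4466 (83.7%) were called there with the same sign, in libraries that both fits share. With a term for those replicates, 4506 genes changed, 2212 higher and 2294 lower, and 481 at least 2-fold. That term is a single shift shared by both replicates and does not take up the difference between them. Limma-trend on TPM called 1538 genes, 936 (60.9%) of them higher against 48.6% on counts; in the 6 libraries alone it called 2716, 1146 higher and 1570 lower.

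The 2 rises with the smallest p were in Ucp2 and Fkbp5, and the 2 falls with the smallest p in Mest and Slit2, among the genes that the rule for named genes admits. Ucp2 (ENSMUSG00000033685.13, chromosome 7, 100493337 to 100502020, protein-coding), a mitochondrial carrier, rose from 83.6 ± 0.616 to 352 ± 9.98 CPM (SD, n = 4), a log2 fold change of 2.07 ± 0.025 (SE, adjusted p = 5.09e-13). Fkbp5 (ENSMUSG00000024222.17, chromosome 17, 28399094 to 28517527) rose from 39.4 ± 1.92 to 269 ± 3.06 CPM, a log2 fold change of 2.77 ± 0.035 (adjusted p = 5.09e-13). Mest (ENSMUSG00000051855.15, chromosome 6, 30723547 to 30748465), an imprinted gene, fell from 1827 ± 40.8 to 624 ± 19.7 CPM, a log2 fold change of -1.55 ± 0.028 (adjusted p = 7.36e-12); 78.0% of its 31-mers are in no other gene. Slit2 (ENSMUSG00000031558.15, chromosome 5, 47983138 to 48307733), a secreted guidance cue, fell from 69.4 ± 2.36 to 20.7 ± 0.330 CPM, a log2 fold change of -1.75 ± 0.033 (adjusted p = 9.27e-12).

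**Figure D1:**
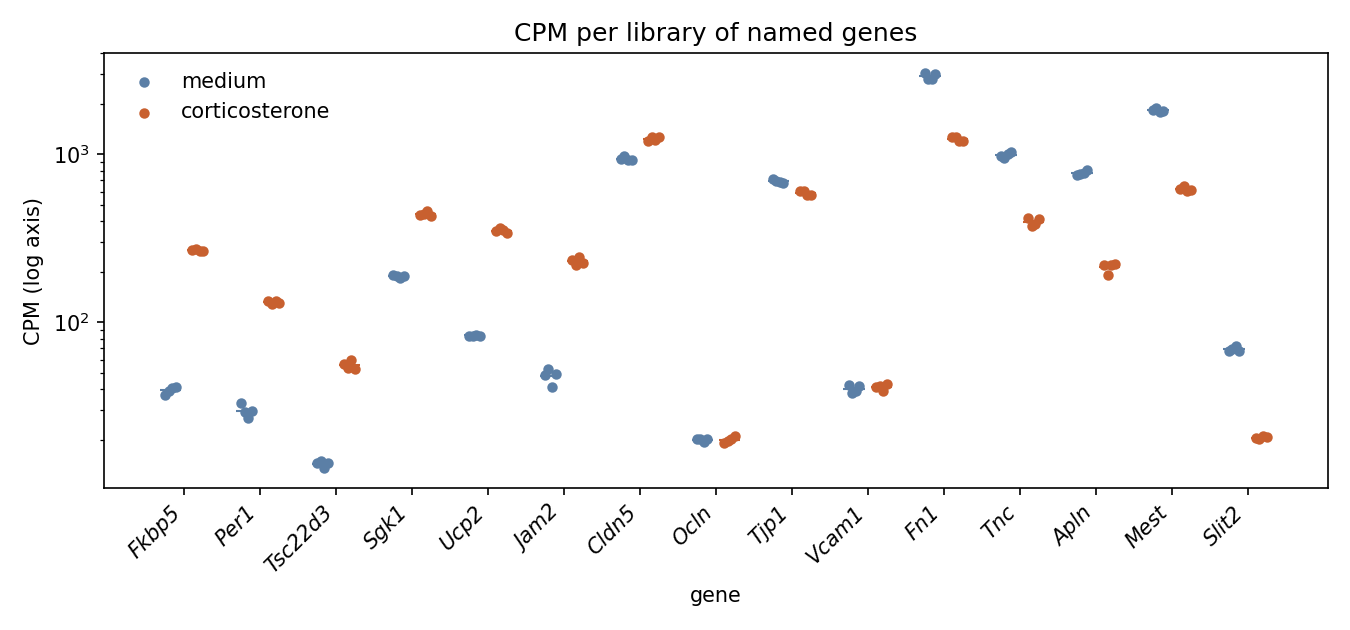
CPM per library (log axis) of 15 named genes, with a point per library, 4 per group, and a short line at each group's mean. Fkbp5 lies near 39.4 CPM in medium and 269 CPM with corticosterone, Fn1 near 2918 and 1239 CPM, and the groups of Ocln and Vcam1 overlap.

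The list of glucocorticoid receptor target genes had 28 measured members, of which 22 rose and 1, Gadd45g, fell (22 and 2 when adjusted over the list alone; camera adjusted p = 7.8e-14, and adjusted p = 0.0169 with an estimated correlation). Sgk1, a kinase that regulates ion transport, rose 2.35-fold and Ddit4, an inhibitor of mTOR signalling, 3.11-fold. Sult1a1, a sulfotransferase, rose 74.7-fold from 0.575 ± 0.141 to 43.4 ± 1.08 CPM, with 88.6% of its 31-mers in no other gene. The list's median log2 fold change was 1.03, as fitted and with the 5 members at 3 counts or fewer in medium set to their bound or to the low end of their interval. Zbtb16, a zinc finger repressor, had 581 counts with corticosterone and 0 in medium, at least 199.6-fold higher against the floor of 3 counts over the medium group. Lcn2, the lipocalin of the acute phase response, had 3916 counts with corticosterone and 1 in medium, a ratio of 4036 (95% interval 723.9 to 159400). This and the other ratios of counts are scaled by the TMM-scaled library totals. The metallothionein gene Mt2 had 455 counts and 1, a ratio of 468.9 (83.74 to 18560). Hif3a had 199 counts and 1, a ratio of 205.1 (36.39 to 8141). In the 6 libraries the list again had 22 rises and 1 fall (camera adjusted p = 2.34e-15).

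Other large rises were in Pi15, a secreted protease inhibitor, 39.7-fold, and in the amino acid oxidase gene Lao1, 80.5-fold as fitted. Lao1 had 0.034 ± 0.041 CPM in medium, with 0 CPM in medium replicates 2 and 4, so its fold rests on few counts. Wnt9b, a Wnt ligand, had 125 counts with corticosterone and 1 in medium, a ratio of 128.8 (95% interval 22.7 to 5128). Among the largest falls, given as the ratio of corticosterone to medium, were 0.113 for Bves, a cell adhesion protein, 0.118 for Gprin2, 0.164 for Esm1, a marker of endothelial tip cells, 0.168 for Lgr6, 0.184 for Ism1, 0.192 for Papln and 0.197 for Bgn, a matrix proteoglycan. Bves (ENSMUSG00000071317.4, chromosome 10, 45335772 to 45372479) fell from 7.62 ± 0.229 to 0.856 ± 0.044 CPM (adjusted p = 2.49e-10). Gprin2 and Bgn had mean CPM of 1.14 ± 0.391 and 3.14 ± 0.642 in medium.

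All 29 members of the cell cycle and DNA replication list fell, also when adjusted over the list alone (camera adjusted p = 3.43e-15; adjusted p = 0.108 with an estimated correlation). Their log2 fold changes lay between -0.46 and -0.20. Mcm3 and Mcm5, parts of the replicative helicase, fell to 0.729 and 0.758 of medium, and Foxm1, a transcription factor of the G2 and M phases, to 0.761. In the 6 libraries all 29 fell (adjusted p = 8.91e-18). Limma-trend on TPM called 12 of the 29 with a median of -0.25, 28 with a median of -0.35 in the 6 libraries, and 20 with a median of -0.52 with one effective length per transcript, where the median of all genes was -0.17.

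Of 18 measured targets of the coactivator YAP and of the serum response factor, 12 fell and 2, Vcl and Fos, rose. Adjusted over the list alone, 13 fell and 2 rose. The list passed camera (adjusted p = 0.00106), but not with an estimated correlation (adjusted p = 0.375). Amotl2, a YAP-binding protein of junctions, fell to 0.499 and the tropomyosin gene Tpm1 to 0.675 of medium. Vinculin, encoded by Vcl, links adhesions to actin; Vcl rose 1.40-fold, with 74.7% of its 31-mers in no other gene. Without corticosterone replicates 1 and 2, 11 fell and 2 rose (adjusted p = 0.000545). Acta2, also on the list of smooth muscle markers, stood at 0.519 of medium, and the fibroblast markers Pdgfra and Col1a1, outside the YAP list, at 0.265 and 0.466. Of 21 TGF-beta and BMP genes, 12 fell and 6 rose, the same counts when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0875; 0.0358 in the 6 libraries). Ltbp1, which binds latent TGF-beta in the matrix, fell to 0.526 of medium, while the matrix protein gene Tgfbi rose 4.80-fold.

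Of 14 leukocyte adhesion molecules, 7 rose and 2, Cd34 and Pecam1, fell, also when adjusted over the list alone (camera adjusted p = 0.0059; adjusted p = 0.108 with an estimated correlation). Jam2 rose from 47.9 ± 4.72 to 232 ± 11.1 CPM (adjusted p = 1.27e-07), the sialomucin gene Podxl 1.69-fold and Mcam 1.45-fold. Selp, an endothelial selectin, rose from 148 ± 2.44 to 214 ± 11.2 CPM (adjusted p = 2.23e-07). Vcam1 and Icam1 did not pass: Vcam1 had 41.3 ± 1.69 CPM with corticosterone and 40.3 ± 2.24 in medium (adjusted p = 0.609), and Icam1 2.22 ± 0.171 and 1.85 ± 0.223 (adjusted p = 0.166). In the 6 libraries 7 rose and 2 fell (adjusted p = 0.00564).

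Junction genes went both ways: of 23 measured, 9 rose and 10 fell (10 and 10 when adjusted over the list alone; camera adjusted p = 0.86). Cldn5 (ENSMUSG00000041378.2, chromosome 16, 18776847 to 18778262) rose from 940 ± 24.1 to 1241 ± 36.0 CPM (adjusted p = 3.44e-07), and Esam, an endothelial adhesion molecule, rose 1.44-fold. Tjp1, the scaffold protein of tight junctions, fell to 0.848 of medium (adjusted p = 1.88e-05). Ocln had 20.1 ± 0.921 and 20.1 ± 0.395 CPM (adjusted p = 0.994). The VE-cadherin gene Cdh5 rose 1.06-fold (adjusted p = 0.0168), a call that ended without corticosterone replicate 1 (adjusted p = 0.0536) and in the 6 libraries (adjusted p = 0.112). It also ended with scaling by library size alone (adjusted p = 0.0614). Of 24 endothelial identity genes, 13 rose and 8 fell (13 and 9 when adjusted over the list alone; camera adjusted p = 0.204). Ly6a and Ly6c1 both rose 2.05-fold, with 68.1% and 53.2% of their 31-mers in no other gene.

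**Figure D2:**
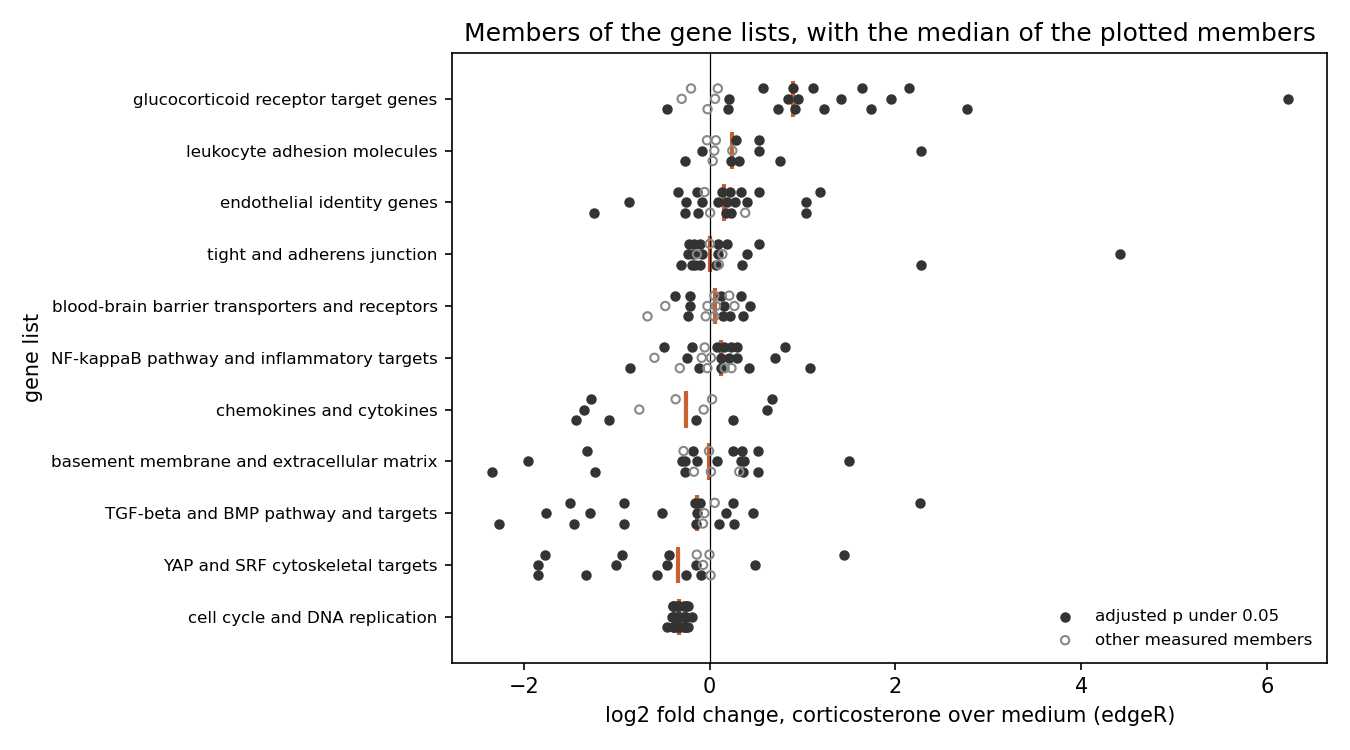
Log2 fold change, corticosterone over medium, of the measured members of 11 gene lists, filled where the adjusted p is under 0.05, with a bar at the median of the plotted members. Left out are 5 glucocorticoid receptor target genes with 3 counts or fewer over the medium libraries, without which that list's median is 0.89; the 29 cell cycle genes lie between -0.46 and -0.20.

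Among 20 barrier transporters and receptors, 7 rose and 4, among them Abcc1, Slc7a5 and Lrp1, fell, also when adjusted over the list alone (camera adjusted p = 0.689). The efflux pump gene Abcc5 rose 1.35-fold. The glucose transporter gene Slc2a1 had 81.4 ± 2.20 CPM with corticosterone and 78.6 ± 1.38 in medium (adjusted p = 0.184), and passed without corticosterone replicate 4 (adjusted p = 0.0471). P-glycoprotein is encoded by Abcb1a and Abcb1b in mice. Abcb1a had 0.530 ± 0.359 CPM with corticosterone and 0.762 ± 0.118 in medium (adjusted p = 0.383), and Abcb1b rose from 86.1 ± 4.38 to 100.2 ± 2.75 CPM (adjusted p = 0.000518), with 84.1% of its 31-mers in no other gene. Of 15 caveolar and transcytosis genes, 4 (Cavin2, Ehd4, Cltb, Picalm) rose and 4 (Cav1, Cav2, Cavin1, Plvap) fell (5 and 4 when adjusted over the list alone; camera adjusted p = 0.787). Plvap, of the diaphragms of fenestrae, fell to 0.806 and Cav2 to 0.836 of medium.

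Of 12 measured chemokines and cytokines, 3 (Ccl2, Cx3cl1, Tgfb1) rose and 5 (Ccl5, Cxcl10, Cxcl12, Csf1, Tnfsf10) fell, also when adjusted over the list alone (camera adjusted p = 0.652). Ccl5, at 0.563 CPM in medium, lost its call in the 6 libraries without corticosterone replicates 1 and 2 (adjusted p = 0.118), where 3 of the list rose and 4 fell. The monocyte attractant gene Ccl2 rose 1.59-fold and Tgfb1 1.53-fold, and Cxcl12 fell to 0.473 of medium. Of 25 NF-kappaB pathway genes, 12 rose and 5 (Nfkb1, Rela, Tnfaip2, Il1r1, Bcl3) fell (13 and 5 when adjusted over the list alone; camera adjusted p = 0.503, and 0.0188 on TPM without a filter). The cyclooxygenase gene Ptgs2 rose 1.63-fold and the interleukin receptor gene Il1r1 fell to 0.553 of medium. Of 27 interferon response genes, 5, among them Ifit2, Ifi27, Ifi35 and Xaf1, rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.689), with Ifit2 at 1.40 and Gbp3 at 0.682 of medium. Without corticosterone replicates 1 and 2, 3 interferon response genes rose and 6 fell, and the calls of Ifi35 (adjusted p = 0.124) and Xaf1 (0.0814) were lost. Of 17 MHC class I genes, 6 rose and 2 (H2-Q4, B2m) fell, also when adjusted over the list alone (camera adjusted p = 0.284, and 0.0103 on TPM with one effective length per transcript); the chaperone genes Calr and Pdia3 rose by log2 fold changes of 0.38 and 0.21.

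Of 23 basement membrane and matrix genes, 9 rose and 9 fell (9 and 10 when adjusted over the list alone; camera adjusted p = 0.689). Fn1 fell from 2918 ± 138 to 1239 ± 39.2 CPM (adjusted p = 2.41e-10). Of 21 proteases and inhibitors, 9 rose and 6 fell (9 and 7 when adjusted over the list alone; camera adjusted p = 0.649). The proteoglycan-degrading proteases Adamts9 and Adamts1 rose 2.99-fold and 2.43-fold, with 88.5% of the 31-mers of Adamts9 in no other gene. Of 26 angiogenic and Notch genes, 9 rose and 11 fell, also when adjusted over the list alone (camera adjusted p = 0.86); the receptor gene Notch4 rose 1.74-fold. Of 16 Wnt pathway genes, 7 rose and 6 fell (7 and 7 when adjusted over the list alone; camera adjusted p = 0.689). Fzd4, the Norrin receptor gene, rose 1.94-fold and the Wnt inhibitor gene Apcdd1 2.03-fold.

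The glucocorticoid receptor gene Nr3c1 (ENSMUSG00000024431.15, chromosome 18, 39410545 to 39519421) fell from 122 ± 1.81 to 96.9 ± 4.53 CPM (adjusted p = 7.27e-06). The mineralocorticoid receptor gene Nr3c2 rose from 1.75 ± 0.434 to 2.98 ± 0.508 CPM (adjusted p = 0.00674), a call lost with limma-trend on TPM without a filter (0.16). Hsd11b1, with a mean of 0.625 counts per library, was not tested. Of 16 genes of corticosteroid receptors, chaperones and metabolism, 4, among them Nr3c2, Hsd11b2 and Ncoa3, rose and 5 (Nr3c1, Fkbp4, Stip1, Ncoa1, Ep300) fell (6 and 5 when adjusted over the list alone; camera adjusted p = 0.824). Of 17 clock genes, 5 (Per2, Arntl, Nr1d1, Bhlhe40, Nfil3) rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.862), with Arntl at 1.75 and Bhlhe40 at 1.93 of medium. Of 23 ER stress and ATF4 targets, 12 rose and 6 fell (13 and 6 when adjusted over the list alone; camera adjusted p = 0.219); the cystine transporter gene Slc7a11 rose 3.30-fold. Of 23 cholesterol genes, 4, among them Hmgcs1, Lss and Stard4, rose and 4, among them Insig1, Sc5d and Acat2, fell, also when adjusted over the list alone (camera adjusted p = 0.86); Sc5d lost its call in the 6 libraries (adjusted p = 0.15). Of 23 glycolysis and hypoxia genes, 7 rose and 4 (Pfkl, Slc16a3, Egln1, Bnip3) fell, also when adjusted over the list alone (camera adjusted p = 0.649), with Epas1 at 1.58 and Pdk1 at 1.53 of medium.

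In 4 lists the median, the mean and the camera direction differed in sign. The medians and means of the log2 fold changes were -0.0041 and 0.064 for receptors and chaperones, with direction down, and -0.051 and 0.074 for the clock, also down. They were 0.00027 and -0.0064 for proteases, with direction up, and -0.0026 and 0.022 for cholesterol genes, also up.

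Of 7 measured pericyte and smooth muscle markers, 1 (Mylk) rose and 2 (Pdgfrb, Acta2) fell, also when adjusted over the list alone (camera adjusted p = 0.689). Mylk rose from 157 ± 6.45 to 188 ± 1.68 CPM (adjusted p = 2.13e-05). Acta2 fell from 1.27 ± 0.444 to 0.652 ± 0.057 CPM, a call that ended without medium replicate 4 (adjusted p = 0.0531). It also ended with a term for corticosterone replicates 1 and 2 (adjusted p = 0.0512) and with limma-trend on TPM without a filter (0.458). Of 4 fibroblast markers, too few to test, 3 (Pdgfra, Col1a1, Fbln1) fell, also when adjusted over the list alone; Pdgfra fell from 18.4 ± 1.00 to 4.87 ± 0.120 CPM and Col1a1 from 2.28 ± 0.298 to 1.08 ± 0.328. Of the astrocyte, microglia and neuron markers 1, Gfap, was measured, at 0.495 ± 0.058 and 0.241 ± 0.113 CPM (adjusted p = 0.0683). With 1 measured member, adjusting over the list alone leaves the unadjusted edgeR p of Gfap, 0.0297, as it is. Adjusted over all genes, Gfap passed without medium replicate 1 (adjusted p = 0.0182).

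Of 13 mitochondrially encoded mRNAs, 1 (mt-Nd2) fell and 0 rose (0 and 0 when adjusted over the list alone; camera adjusted p = 0.787), and mt-Nd2 lost its call without corticosterone replicate 1 (adjusted p = 0.0501) or 4 (0.103) and without medium replicate 1 (0.0739), 2 (0.0738) or 3 (0.0846). In the 6 libraries without corticosterone replicates 1 and 2, 4 (mt-Nd3, mt-Co1, mt-Co2, mt-Co3) rose and 0 fell, with mt-Nd2 at an adjusted p of 0.0627. The gene mt-Nd1 did not pass (adjusted p = 0.0792) but did without corticosterone replicate 2 (adjusted p = 0.0316) or 4 (0.0244). Of 30 ribosomal protein genes, 5, among them Rpl10a, Rpl18, Rpl37 and Rps3, rose and 0 fell (0 and 0 when adjusted over the list alone; camera adjusted p = 0.503, and 0.0164 when genes that share sequence are summed). Of the 30, 3 rose in the 6 libraries, and the calls of Rpl18 (adjusted p = 0.136) and Rps3 (0.0848) were lost. Rpl10a stood at 1.16 of medium and lost its call without medium replicate 3 (adjusted p = 0.0504). Rpl37 stood at 1.18 of medium and lost its call without corticosterone replicate 2 (adjusted p = 0.0558) or 3 (0.0672) and without medium replicate 1 (0.08), 2 (0.0834) or 3 (0.0503). Under limma-trend on log2(TPM + 1), Rpl10a had a log2 fold change of -0.13 and did not pass (adjusted p = 0.63).

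Corticosterone replicates 1 and 2 stood apart from the other libraries, most visibly in genes that share sequence. The gene mt-Co2, with 0% of its 31-mers in no other gene, had 66.8 CPM in corticosterone replicate 2 and 2317 to 2761 CPM in the other 7 libraries, while Gm28661, a nuclear copy of mitochondrial sequence, had 2722 CPM in that replicate and at most 31.8 CPM elsewhere. In principal components of all tested genes, PC1 (44.87% of variance) set corticosterone replicates 1 and 2 at -48.44 and -43.62. Replicates 3 and 4 lay at -9.768 and -8.279 on it, and the medium libraries at 26.5 to 28.66. PC2 (26.2% of variance) parted corticosterone replicates 1 and 2 from each other, at 45.98 and -47.07. In the 9004 genes with 95% or more unique 31-mers, PC1 (72.3%) parted the groups, and PC2 (7.89%) set corticosterone replicate 2 at -17.61 against 3.71 to 7.44 for the other corticosterone replicates. Of the 499 genes changed at least 2-fold, 398 had that share of unique 31-mers. On TPM, which carry the effective lengths, the calls of Mcm3, Cav2, Ccl2, Ncoa3, Pdia3, Tjp1, Mylk, Rpl10a, Cdh5, mt-Nd2 and Rpl37, among others, were lost with limma-trend on log2(TPM + 1) (adjusted p from 0.0539 for Ncoa3 to 0.704 for Rpl37). Some of their log2 fold changes were as large on TPM as on counts, 0.24 on both for Ncoa3, or larger, 0.55 against 0.21 for Pdia3 and 0.20 against 0.09 for Cdh5. With one effective length per transcript, those of, among others, Cldn5 (adjusted p = 0.525), Esam (0.0982), Mcam (0.123), Vcl (0.244), Tgfb1 (0.101), Ptgs2 (0.122) and Epas1 (0.0718) were also lost, with the same sign and smaller log2 fold changes, 0.14 against 0.40 for Cldn5. The median over all genes was -0.168 in that setting, so part of each drop goes with a shift of the whole scale.

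**Figure D3:**
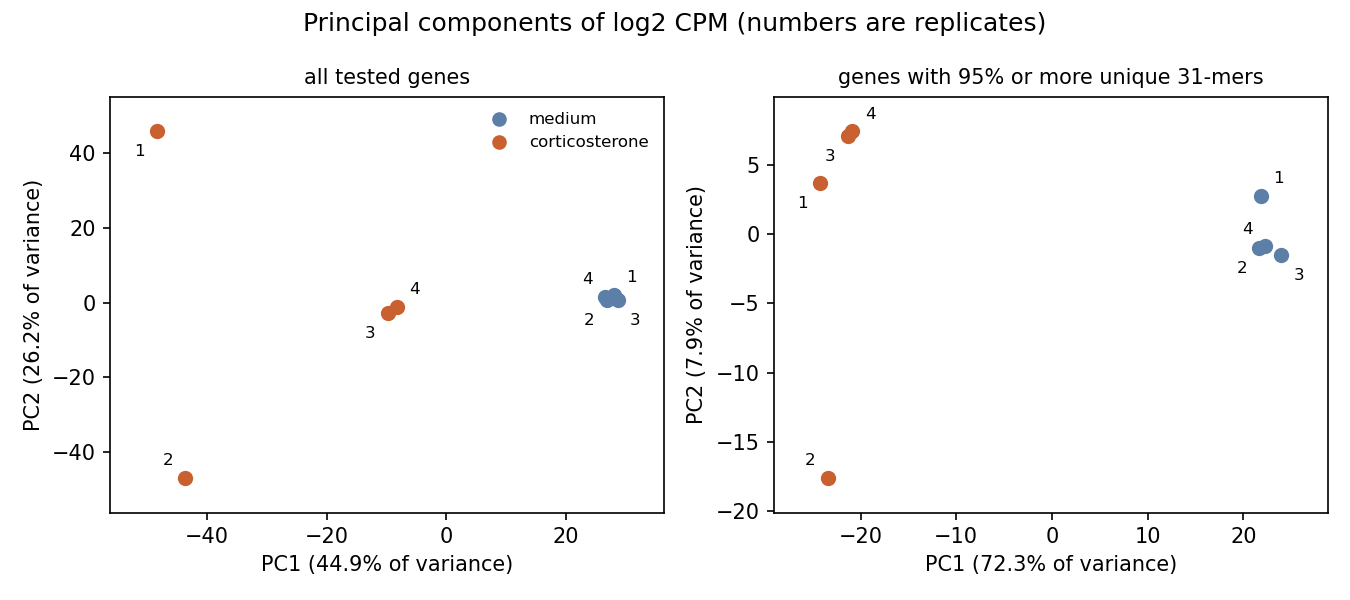
Principal components PC1 and PC2 of log2 CPM per library, for all tested genes (left) and for the 9004 genes with 95% or more unique 31-mers (right); each point is a library and the number beside it its replicate. On the left corticosterone replicates 1 and 2 lie at 45.98 and -47.07 on PC2; on the right the groups lie at -20.9 or below and at 21.7 or above on PC1.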

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

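Several tests in this part were chosen after the result they bear on had been seen: those of another culture state, of library depth and of the excess over replicates 3 and 4, those of the quantification and of replication against mitosis genes in the cell cycle list, and the splits taken list by list.

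The values of 82 named genes in both groups were searched: in 11 of 164 groups of 4 libraries (6.71%, where chance gives about 1 in 20) a single library lay far from the other 3; 4 measures of the libraries gave none. Lcn2 and Mt2 each had 0.02119 CPM in medium replicate 1, and Hif3a and Wnt9b each 0.05025 CPM in medium replicate 3, with 0 CPM in the other medium libraries. These are single counts. A single count beside libraries at 0 is always found by this search, so the rate of 1 in 20 does not cover these groups. The share of 6.71%, which includes them, therefore shows no excess over chance. Apln had 192.4 CPM in corticosterone replicate 2 against 219.6 to 223.9, and Ifit2 23.71 CPM in that library against 20.81 to 21.09. Mcm5 had 212.2 CPM in corticosterone replicate 1 against 223.6 to 225.1, and Papln 2.637 CPM in corticosterone replicate 4 against 1.804 to 1.921. Abcc5 had 131 CPM in medium replicate 1 against 113.4 to 114.8. In medium replicate 3, Epas1 had 307.6 CPM against 354.8 to 363.1 and Gbp3 9.547 CPM against 12.47 to 12.59. In each of these 11 genes every library of one group still lay above every library of the other, and no explanation was tested. A signal also appeared in the effective length, a column that the comparison does not use: it equalled the transcript length plus 1 in 100% of transcripts of 1000 nt or more in corticosterone replicates 1 and 2, and in 0% in the other 6 libraries.

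Corticosterone replicates 1 and 2 stand apart from the other libraries, and reads moved among genes that share sequence may account for much of it. Whether the other effective length moved them cannot be told from sums of families. Both replicates carry that length, yet their log2 CPM correlated less with each other (r = 0.956) than with replicates 3 and 4 (0.969 to 0.973). They also shared a departure: on PC1 of all tested genes they lay at -48.44 and -43.62, against -9.768 and -8.279 for replicates 3 and 4. When genes that share 31-mers were summed, 55.5% of the CPM difference from replicates 3 and 4 was left, which missed the bound of 50% set beforehand but lay below the 91.8% of the lowest of 100 random groupings; of the excess over the difference between replicates 3 and 4 themselves, 75.9% went. Another state of these cultures stays open: 1.78% of genes with mostly unique 31-mers differed at least 2-fold against 17.9% of the others, but replicates 3 and 4 alone gave 0.378% and 2.77%, so the bound set for the ratio of these shares would have been met without any such state, and in the mostly unique genes PC2 still set replicate 2 apart. Library depth is argued against, with 0 of the 2 totals outside the range of the other 6. Both replicates are in the corticosterone group, so for genes that share sequence the quantification and corticosterone are told apart through replicates 3 and 4 alone.

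The cell cycle genes were lower with corticosterone by a median log2 fold change of -0.33. The quantification of corticosterone replicates 1 and 2 is argued against, as all 29 members fell in the 6 other libraries. The choice among the scalings tried is argued against too, as the list's median nearest to 0 was -0.323. Those scalings set the median over all genes only between 0.000643 (RLE) and -0.0352 (library size), so a larger shift of scale was not tested. Whether a smaller share of cells was cycling cannot be told: the medians of mitosis and replication members differed by -0.0142, but 83.5% of random assignments of members to phases also met the bound of 1 SD (0.0662). No assignment could have reached the bound of 2 SD set for the opposite outcome (at most 0.115, against 0.132), so that test decides nothing. The number of cells was not given in the sources used here, so a lower transcript level in each cycling cell stays open, as does a difference in density between cultures.

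Chance is argued against, but not excluded, for the counts of genes. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many changed genes (5337, highest other 0) and genes changed at least 2-fold (499, highest other 0). The same held for higher genes (2596, highest other 0) and lower genes (2741, highest other 0). A share of 1 in 35 is the smallest this design allows, and the replicates may not be separate cultures. Every other split mixes corticosterone and medium libraries within its groups, which adds the difference between them to the spread. The size of the gap to 0 therefore says nothing about chance. At an unadjusted p under 0.05, another edgeR split gave at most 893 genes against 6375. For the number of lists chance is not argued against, as 7 of the 35 splits gave 4 or more lists (real 4, highest other 7). Of these, 6 are among the 16 splits that leave 3 libraries of a group together, and 0 among the 18 that mix the groups evenly, where the most was 3. Taken list by list, 1 of the 35 splits, the real one, gave as small a camera p for glucocorticoid receptor targets (6.24e-15, smallest other 1.9e-07), leukocyte adhesion molecules (0.000944 and 0.00374), YAP and SRF targets (0.000128 and 0.000736) and the cell cycle (1.37e-16 and 1.3e-11). These p use a preset correlation; with an estimated one the last 3 lists did not pass (adjusted p = 0.108, 0.375 and 0.108).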

How the results depend on the processing

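The 6 alternatives for the effective lengths (the 6 libraries, a term for corticosterone replicates 1 and 2, families, mostly unique genes, and both other TPM settings) were chosen after seeing the data; the others were planned. On counts, the planned and added alternatives stayed within 1.5 times the reported counts of changed, higher, lower and 2-fold genes. Without each library in turn, changed genes ranged from 4781 to 5116, higher from 2359 to 2551, lower from 2414 to 2609 and 2-fold from 496 to 557, lists stayed at 4 (DESeq2 and the other quasi-likelihood settings give no list test), and the difference in totals ranged from -3.71 to 5.11 M (1e+06 counts).

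On TPM the counts fell. Limma-trend on log2(TPM + 1) gave 1538 changed genes, 936 higher, 602 lower and 269 at least 2-fold; log2(TPM + 0.1) gave 1509, 932, 577 and 348, the last within 1.5 times of 499; without a filter log2(TPM + 1) gave 1317, 808, 509 and 260. One effective length per transcript gave 1001, 300, 701 and 242, with a median log2 fold change over all genes of -0.168, and TPM of the 6 libraries 2716, 1146, 1570 and 230. The cause was not tested: one effective length per transcript lowered the count further, and leaving out corticosterone replicates 1 and 2 removes their moved reads as well as their effective lengths. Lists past the threshold were 1 with an estimated correlation and 15 with fry, which asks whether a list's genes move one way without comparing them with other genes. Of the named genes, Rpl10a changed sign on TPM without passing, at -0.13 with pseudocounts 1 and 0.1 and also without a filter. Its limma-trend adjusted p was 0.625 to 0.748 there, and the cause was not tested. With one effective length, Ncoa3 (-0.045, limma-trend adjusted p = 0.862) and Cdh5 (-0.16, adjusted p = 0.428) changed sign without passing. Both lie above the median of -0.168 over all genes in that setting, so neither fell relative to that median. Of the 85 named genes, 29 lost a call under at least 1 alternative and 3 gained one. A replicate block gave 4880 genes. Deviations from the group mean correlated at -0.0374, 0.0302, -0.0527 and -0.0507 between same-numbered libraries, which gives no sign of pairing. Pairing is not excluded, because the corticosterone mean includes replicates 1 and 2, whose departures can hide it. At the totals, dispersions and sample size of these libraries, 64% of 1.5-fold changes were called in simulated data. Far fewer genes changed there than in the data, which makes the adjusted threshold stricter, so that share may be too low. Depth itself was not varied.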

Other observations

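The genes and gene families in this part were chosen after their values had been seen, by a ranking of abundant genes outside the lists and by one scan of 141 families of gene symbols. Among genes of at least 50 CPM outside the lists, Ace, the angiotensin-converting enzyme of the endothelial surface, rose 7.31-fold, from 90.6 ± 3.63 to 663 ± 23.5 CPM (SD, n = 4, edgeR adjusted p = 5.09e-13). Itgb3, an integrin subunit that binds matrix, rose 3.39-fold to 990 ± 13.5 CPM, and Lyve1, a hyaluronan receptor, 4.26-fold to 407 ± 13.8 CPM. Ednrb, an endothelin receptor, rose 5.04-fold, Igfbp3, a carrier of insulin-like growth factors, 4.57-fold, Pmp22 7.21-fold and the phosphatidate phosphatase gene Lpin3 6.21-fold. The nuclear receptor gene Nr4a1 rose 3.03-fold. Among falls, Zyx, a protein of focal adhesions, went to 0.465 of medium, the activin subunit gene Inhbb to 0.282, the interleukin receptor gene Il4ra to 0.455 and Hoxd8 to 0.449.

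Of the 141 families with at least 10 measured members, 3 passed camera, and 0 did with an estimated correlation (adjusted p = 0.726 for each of the 3). Of 10 Mcm genes, which include the replicative helicase, 8 fell and 0 rose (camera adjusted p = 0.000752); 6 of them are also in the cell cycle list. Of 10 Adamts proteases, 7 rose and 0 fell (camera adjusted p = 0.002), with Adamts6 at 6.49, Adamts5 at 2.21 and Adamts4 at 1.91 of medium. Of 34 Cep genes of the centrosome and cilium, 17 fell and 1, Cep83, rose (camera adjusted p = 0.00961). All 3 passed in the 6 libraries without corticosterone replicates 1 and 2 as well.

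The gene mt-Atp6, with 0.46% of its 31-mers in no other gene, had 957.9 CPM in corticosterone replicate 2, 4000 CPM in corticosterone replicate 1 and 1936 to 2166 CPM in the other 6 libraries. Gm28437 had 1628 CPM in corticosterone replicate 2 and 0 CPM in the other 7 libraries.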
